A study of Homo sapiens with 6 samples.

How the data were processed

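Gene-level counts were used for 6 RNA-seq libraries of human C4-2 prostate cancer cells, 3 of the parental line and 3 of an enzalutamide-resistant line (Enz-R). Reads were 150 bp paired-end. Reads were aligned with HISAT2 to GRCh38, per the submitters' processing notes. The version of HISAT2, the counting tool, its annotation and its strand setting are not given in the sources used here, and the library kit is not stated to mark strand. The deposited table holds raw counts, whole numbers per gene and library, which the authors made from the alignments before any scaling. No reads were realigned here. The table has 59565 loci, of which 58676 have Ensembl identifiers, all in GENCODE 29, and 889 are unannotated loci. Identifiers were given GRCh38 positions from GENCODE 29. The 41937 that have a current symbol were given it from a separate list of gene names, and the others kept their GENCODE 29 name. Library totals ran from 15673404 to 28247038 counts. Between replicate pairs the chi-square per degree of freedom of the counts was 4.30 to 10.1, so the libraries differ by more than counting error.

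Samples were grouped by the labels, and the lists, panel, tests and alternatives below were fixed before the data were examined unless stated. Parental and Enz-R libraries were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit, glmQLFTest, no covariate). P-values were adjusted by Benjamini-Hochberg over the 19029 genes that passed the filter, with 0.05 as the threshold. Mean CPM and its SD use library totals scaled by the TMM factors, and log2 fold changes are those of the fit. Their SE was derived from the fold change and the F statistic of the test, and can be too small where a group holds few counts. The common biological coefficient of variation was 7.20%. Genes with 1 to 3 counts in a group are given as a ratio of group sums with a 95% counting interval. Such intervals cover counting error only.

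A total of 35 gene lists was fixed, covering androgen-regulated and glucocorticoid-regulated genes, androgen enzymes, prostate lineages, other cell types, the cell cycle, DNA repair, metabolism, stress, immune and signalling pathways, histones, ribosomal proteins and mitochondrially encoded transcripts. The 34 lists with at least 5 tested members were tested with limma 3.58.1 camera (preset inter-gene correlation 0.01, log2 CPM with prior count 2), adjusted over the lists. The alternatives were camera with an estimated correlation and fry. The fry p-value asks whether the genes of a list move on balance one way and its mixed p-value whether they move in either direction, and neither compares them with other genes. Members were also adjusted over the list alone. Named genes are a fixed panel of 22, the 12 largest rises and 12 largest falls among called genes with non-overlapping groups and at least 5 CPM in the higher group, and up to 3 risers and 3 fallers per list with the same minimum. Clone names, pseudogenes and antisense genes were excluded.

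Alternatives were the replicate number as a block, leaving out each library in turn, DESeq2 size factors and total count scaling, no filter beyond a nonzero total, at least 50 counts in 3 libraries, DESeq2 1.42.0, and limma-voom. After the data were seen, 3 more were added: GC content and transcript length regressed out of each library by splines with 5 degrees of freedom, counts thinned to the smallest library, and mitochondrially encoded genes left out before scaling. GC content and length were known for 96.3% of tested genes. Also chosen after the values were seen were tests of 175 gene families by symbol stem and a scan of windows of 25 neighbouring protein-coding genes. The scan took genes with a mean of at least 1 CPM on chromosomes 1 to 22 and X, with p from 100000 random gene sets and a comparison with 1000 random gene orders. It used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.

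The methods were tested on simulated data, with 19029 genes for the fit, camera and the GC correction and 12722 for the scan of windows. The fit recovered 64.2% of planted 1.5-fold, 77.6% of 2-fold and 95.5% of 4-fold changes, with 8 false calls among 18829 unchanged genes. These changes were planted in 67, 67 and 66 genes, up or down at random. Scaling and false calls were therefore not tested for data in which most genes change. Camera found the planted list and called 0 of 33 others. The genes were simulated independently of each other, so false list calls that come from correlation between genes were not tested. A planted GC trend gave 2576 calls without and 2 with the correction. A planted run of neighbouring genes ranked 1 of 498 windows. DNA copy number, variants and splicing were not analysed here. Some genes and lists that the rules above cover are not reported here.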

Results

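RNA-seq gene counts were available for C4-2 cells, a human prostate cancer line derived from LNCaP, and for an enzalutamide-resistant line of them, labelled Enz-R. Each group held 3 libraries. The totals were 28247038, 19400321 and 19563706 counts in the parental libraries and 23351394, 17429253 and 15673404 in the Enz-R libraries. Mitochondrially encoded genes took 10.2% ± 1.27 of the counts in the parental group and 14.9% ± 0.519 in the Enz-R group (SD, n = 3 each). Across 19029 tested genes, log2 CPM correlated at 0.990 to 0.993 between libraries of a group and at 0.926 to 0.936 between groups. The first principal component held 85.4% of the variance and separated the groups. The labels name no separate cultures, so p-values measure only the spread between these libraries, which may be technical. They also do not say whether the Enz-R cells were in enzalutamide when collected.

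The comparison asks how the transcriptome of the resistant cells differs from that of the parental cells. In Enz-R, transcripts of androgen-induced genes such as TMPRSS2, FKBP5, SLC45A3 and TRPM8 were lower. Transcripts of the steroid-glucuronidating enzymes UGT2B15 and UGT2B17 and of the growth factor-binding protein IGFBP3 were higher. Most tested members of the DNA replication (17 of 20), unfolded protein response (11 of 15) and amino acid response (14 of 17) lists were lower, and most of the ribosomal protein (23 of 23), mitochondrially encoded (13 of 13) and MHC class I (11 of 15) lists were higher. Limma's camera test called these 6 lists with its preset correlation between genes. It called none of them once that correlation was estimated (adjusted p = 0.641 with an estimated correlation for each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6173 genes were higher and 6150 lower in Enz-R at adjusted p under 0.05, together 64.8% of those tested. At least 2-fold changes were found in 2095 of the higher and 1647 of the lower genes. The 3 libraries of one group all lay above the 3 of the other for 13111 genes, or 68.9% of those tested, where chance gives 10%. List adjusted p-values below are camera's unless another test is named. Other values are log2 fold changes of Enz-R over parental ± SE, or mean CPM ± SD with n = 3 per group, and positions are on GRCh38. That SE is derived from the F statistic of the test. It can be too small for genes with few counts in a group, as many of the largest rises and falls have.

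Among the largest rises, IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874), which binds insulin-like growth factors, went from 2.12 ± 0.226 to 308 ± 24.9 CPM, a log2 fold change of 7.19 ± 0.10 (adjusted p = 6.28e-16). CRISP3, a secreted protein of the prostate and other glands, rose from 1.09 ± 0.140 to 80.7 ± 3.97 CPM (6.19 ± 0.11), and NR2F1, an orphan nuclear receptor, from 0.757 ± 0.0763 to 37.2 ± 11.4 CPM (5.60 ± 0.24). The efflux transporter gene ABCC11 rose by 6.74 ± 0.22, the amino acid transporter gene SLC38A5 by 5.58 ± 0.24 and the cancer-testis antigen gene CTAG2 by 6.40 ± 0.12. TTPA, which encodes the vitamin E transfer protein, rose by 7.67 ± 0.29 and the potassium-chloride cotransporter gene SLC12A5 by 6.98 ± 0.34, each from 4 counts over the parental group. Their SEs understate the counting error of so few counts. The homeobox gene HOXD13 had 2 counts over the parental group and 327 over Enz-R, a ratio of 208-fold (95% counting interval 57.2 to 1726), and RNF217 had 3 and 369 counts, a ratio of 157-fold (95% counting interval 53.2 to 763). CTAG2 shares sequence with its close relatives CTAG1A and CTAG1B, so its counts are uncertain. The intervals cover counting error only.

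The largest falls were led by PTGFR (ENSG00000122420, chromosome 1, 78303884 to 78539749), the prostaglandin F receptor gene, with 3460 counts over the parental group and 3 over Enz-R, lower by 906-fold (95% counting interval 309.8 to 4396). The potassium channel gene KCNJ3 had 543 and 2 counts, lower by 213-fold (95% counting interval 58.8 to 1766), and the zinc finger gene ZNF728 had 488 and 3 counts, lower by 128-fold (95% counting interval 43.5 to 622). The collagen gene COL12A1 fell from 174 ± 2.82 to 2.83 ± 0.390 CPM (-5.96 ± 0.09, adjusted p = 6.28e-16), and ST6GALNAC1, a sialyltransferase of the sialyl-Tn antigen, from 59.9 ± 4.24 to 0.717 ± 0.291 CPM (-6.33 ± 0.15). PASD1 (-7.12 ± 0.16), ADGRL2 (-6.87 ± 0.22), ZNF385B (-6.06 ± 0.20), the BMP receptor gene BMPR1B (-6.05 ± 0.28), the nicotinamide methyltransferase gene NNMT (-5.93 ± 0.26) and GULP1 (-5.83 ± 0.23) completed the 12 largest falls together with TRPM8, which is given with the androgen-induced genes.

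Of 25 tested androgen-induced genes, 23 fell and 2 rose, with a median log2 fold change of -1.50. By camera the androgen-induced list was lower in Enz-R than other genes (adjusted p = 7.92e-09). That call was lost when the correlation between genes was estimated (adjusted p = 0.641 with an estimated correlation, unadjusted p = 0.0243). The fry test, which makes no comparison with other genes, gave the list adjusted p = 3.58e-05. TMPRSS2, a serine protease gene, fell from 1408 ± 54.9 to 331 ± 15.7 CPM (-2.09 ± 0.07, adjusted p = 2.29e-12). The FK506-binding protein gene FKBP5 fell from 157 ± 13.1 to 32.3 ± 1.59 CPM (-2.28 ± 0.08). The largest falls of the list were those of the cation channel gene TRPM8 (-6.73 ± 0.15), SLC45A3 (-3.84 ± 0.09) and PMEPA1 (-2.75 ± 0.06). KLK3 (ENSG00000142515, chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, fell less, from 4768 ± 249 to 2533 ± 63.9 CPM (-0.91 ± 0.08), as did KLK2 (-0.59 ± 0.06). The 2 members that rose were KLK4 (0.56 ± 0.08) and, at low counts, HPGD (2.08 ± 0.36), which was named after its value was seen.

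**Figure D1:**
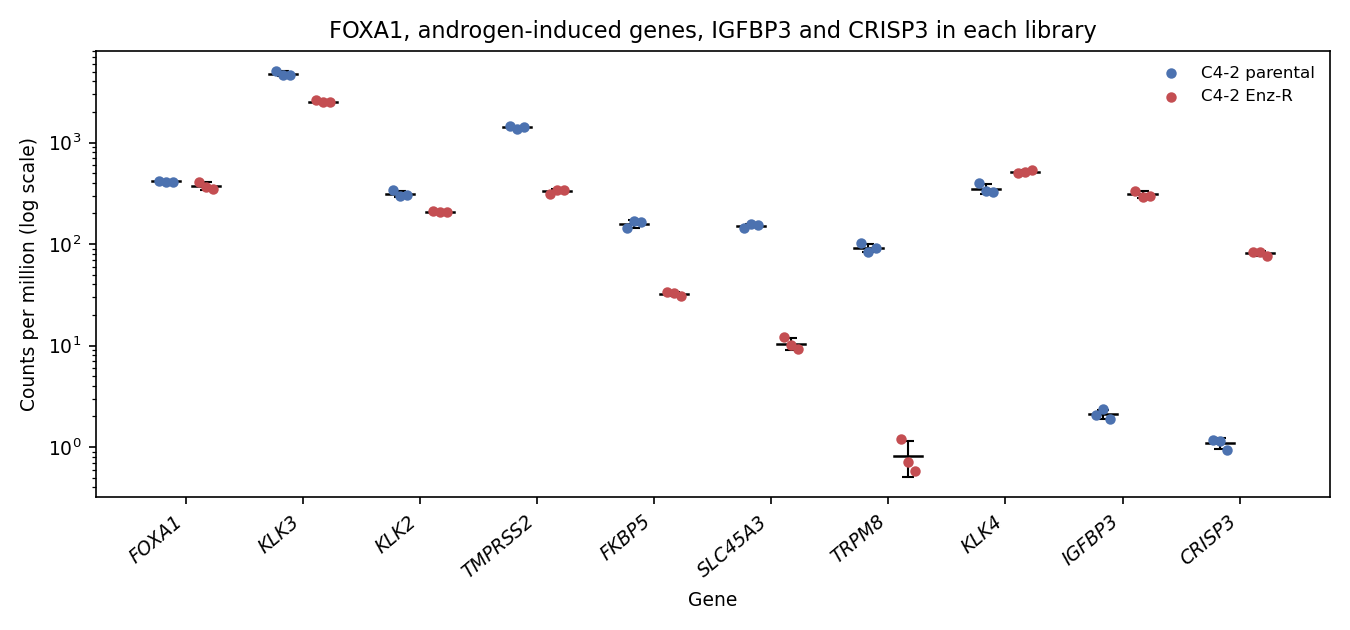
CPM (log axis) of 10 genes in each library, with points for the 3 libraries of a group and black bars for the group mean ± SD. The FOXA1 levels of the groups lie close together, the androgen-induced genes KLK3 to TRPM8 are lower in every Enz-R library than in every parental library (TRPM8 from 92.0 ± 8.82 to 0.825 ± 0.320 CPM), and KLK4, IGFBP3 (from 2.12 ± 0.226 to 308 ± 24.9 CPM) and CRISP3 are higher.

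Of 8 tested androgen-repressed genes 4 were higher and 2 lower, and the list was not called by camera (adjusted p = 0.185). Over the alternatives 3 to 6 genes of the list were higher and 2 lower. UGT2B17 rose from 0.168 ± 0.115 to 24.4 ± 1.18 CPM (7.20 ± 0.21) and UGT2B15 from 0.482 ± 0.372 to 22.1 ± 2.15 CPM (5.55 ± 0.24). Both enzymes conjugate androgens with glucuronic acid. Their sequences are near-identical, so reads may be split between them and the separate values are uncertain. DDC, the aromatic amino acid decarboxylase gene, fell by 9.52-fold (-3.25 ± 0.08), and CAMK2N1 by 1.38-fold (-0.46 ± 0.09). CAMK2N1 (chromosome 1, 20482391 to 20486220) lies in the lowered window of neighbouring genes on chromosome 1 that is given under other observations. Its fall was smaller than the median of that window. Among androgen synthesis and inactivation enzymes, 3 of 12 were higher, 1 lower and 8 not called, and the list was not called (adjusted p = 0.558). AKR1C3, which converts androstenedione to testosterone, rose from 0.124 ± 0.0665 to 1.13 ± 0.402 CPM (3.06 ± 0.47). It stayed near 1 CPM and shares sequence with its AKR1C relatives. HSD3B1 had a value of -0.20 ± 0.36 (adjusted p = 0.631), and HSD17B10, a mitochondrial dehydrogenase gene, was higher by 0.32 ± 0.07. The glucocorticoid receptor gene NR3C1 had 20 counts over the parental and 9 over the Enz-R group and was below the count filter. Of 12 tested glucocorticoid-induced genes, 4 were higher and 5 lower (list adjusted p = 0.992). The metallothionein gene MT2A (2.29 ± 0.13), BCL6 (1.93 ± 0.08) and GADD45B (1.55 ± 0.09) rose, and ZBTB16 (-2.59 ± 0.09), KLF9 (-0.70 ± 0.07) and ERRFI1 (-0.56 ± 0.07) fell.

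Luminal lineage genes went both ways, with 4 of 17 higher and 10 lower, and the list was not called (adjusted p = 0.120). The keratin genes KRT18 (0.70 ± 0.07) and KRT8 (0.40 ± 0.06) and AMACR (0.61 ± 0.13) rose. The peptidase gene DPP4 (-2.77 ± 0.12), KRT19 (-0.91 ± 0.13), the prostate homeobox gene HOXB13 (-0.80 ± 0.07) and FOLH1 (-0.49 ± 0.06), which encodes prostate-specific membrane antigen, fell. The pioneer factor gene FOXA1 stood at -0.15 ± 0.07 and was not called (adjusted p = 0.0673), with adjusted p of 0.00234 to 0.233 over the alternatives. Of 24 neuroendocrine genes only 9 passed the count filter. Of these 9, 5 rose and none fell, with a median of 0.55, and camera called the list higher (adjusted p = 0.0401, and adjusted p = 0.641 with an estimated correlation). PEG10 rose from 2.16 ± 0.238 to 14.2 ± 2.46 CPM (2.69 ± 0.16), the neuronal enolase gene ENO2 from 33.7 ± 6.04 to 97.1 ± 3.37 CPM (1.52 ± 0.10) and the synaptophysin gene SYP from 2.33 ± 0.406 to 5.24 ± 0.689 CPM (1.17 ± 0.18). SYP lies on chromosome X from 48.9 to 49.9 Mb, in a window of 25 neighbouring genes with a median log2 fold change of 1.06, so its rise is about that of its neighbours. The chromogranin gene CHGA had 29 counts over the parental and 6 over the Enz-R group, too few to be tested, and SOX2 had a value of -0.23 ± 0.40 (adjusted p = 0.621). Leaving out 1 library at a time, the adjusted p of the neuroendocrine list ranged from 0.0350 to 0.213 and the call was kept only without parental replicate 3.

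Basal lineage genes were 5 of 11 higher and 3 lower (list adjusted p = 0.809), with ITGB4 (1.17 ± 0.07) and LAMA3 (0.58 ± 0.06) among those that rose and DST (-1.34 ± 0.08) and ITGA6 (-0.26 ± 0.07) among those that fell. Of 8 mesenchymal genes 4 fell and none rose (list adjusted p = 0.185), among them the vimentin gene VIM (-1.25 ± 0.19), the fibronectin gene FN1 (-0.52 ± 0.07) and ITGA5 (-0.41 ± 0.07). Stem cell genes were 3 of 8 higher and 3 lower (list adjusted p = 0.947). SOX9 (1.66 ± 0.09) and the Polycomb gene BMI1 (0.80 ± 0.07) rose, while the nestin gene NES (-2.83 ± 0.08), KLF4 (-1.78 ± 0.12) and POU5F1 (-1.47 ± 0.17), which has several pseudogenes that can share reads, fell. Of 5 fibroblast markers 1 was lower (the collagen gene COL1A1, -0.23 ± 0.07; list adjusted p = 0.775), and of 5 endothelial markers 2 were lower, or 1 adjusted over the list alone (VWF, -2.96 ± 0.24; list adjusted p = 0.320, and 0.0138 by limma's fry).

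DNA replication and S phase genes were lower in Enz-R. Of 20 members 17 fell and none rose, with a median of -0.53 (camera adjusted p = 0.00107; adjusted p = 0.641 with an estimated correlation). MCM2, a subunit of the replicative helicase, fell from 90.5 ± 9.31 to 25.8 ± 2.52 CPM (-1.81 ± 0.09), the cyclin gene CCNE2 by 2.17-fold (-1.12 ± 0.12) and the thymidylate synthase gene TYMS by 1.83-fold (-0.87 ± 0.10). TYMS overlaps genes on the other strand, whose reads cannot be told apart from its own without strand. Mitosis genes were 14 of 20 lower and 4 higher, and their list was not called (adjusted p = 0.0589). MKI67 (-0.77 ± 0.07), HMMR (-0.73 ± 0.07) and TPX2 (-0.69 ± 0.06) fell, whereas CDK1 (0.93 ± 0.09), AURKB (0.46 ± 0.09) and UBE2C (0.38 ± 0.07) rose. Homologous recombination genes split into 6 higher and 6 lower of 17 (list adjusted p = 0.992), with RAD51C (0.54 ± 0.07), BARD1 (0.50 ± 0.06) and ATM (0.30 ± 0.06) higher and RAD54L (-0.91 ± 0.14), BRCA1 (-0.69 ± 0.09) and XRCC2 (-0.57 ± 0.08) lower. Replication-dependent histone genes, which largely lack poly(A) tails and share sequence, were 4 of 8 lower (list adjusted p = 0.286), including H2BC12 (-0.80 ± 0.12), H4C8 (-0.53 ± 0.13) and H2AC6 (-0.45 ± 0.08). RB1, which restrains entry into S phase, was lower by 0.24 ± 0.07 on the log2 scale (adjusted p = 0.00873), with adjusted p of 0.00133 to 0.444 over the alternatives. The oncogene MYC was higher by 0.26 ± 0.09 (adjusted p = 0.0147), with adjusted p of 0.00121 to 0.121 over the alternatives.

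Genes of the unfolded protein response and of the ATF4 amino acid response were lower in Enz-R. Of 15 unfolded protein response genes 11 fell and none rose, with a median of -0.42 (camera adjusted p = 0.00373; adjusted p = 0.641 with an estimated correlation). The chaperone gene HYOU1 fell from 330.0 ± 14.4 to 99.7 ± 7.14 CPM (-1.73 ± 0.07), and the disulfide isomerase genes PDIA6 and PDIA4 by 2.40-fold and 1.83-fold. Of 17 ATF4 response genes 14 fell and 2 rose, with a median of -0.89 (camera adjusted p = 0.00128; adjusted p = 0.641 with an estimated correlation). The amino acid transporter gene SLC7A5 fell from 349.6 ± 2.46 to 61.4 ± 8.99 CPM (-2.50 ± 0.09), the asparagine synthetase gene ASNS by 2.81-fold and the glutathione-degrading CHAC1 by 2.53-fold. The 2 that rose were the stress-induced transcription factor genes DDIT3 (1.26 ± 0.08) and ATF3 (1.17 ± 0.07). Glycolysis and hypoxia genes were lower, with 12 of 18 lower and 2 higher, or 13 lower adjusted over the list alone (camera adjusted p = 0.0369; adjusted p = 0.682 with an estimated correlation). BNIP3 fell from 756 ± 90.6 to 177 ± 15.5 CPM (-2.10 ± 0.09), and the glucose transporter gene SLC2A1 (-1.08 ± 0.12) and PFKFB3 (-0.94 ± 0.11) fell, while EGLN3 rose (0.88 ± 0.15). Leaving out 1 library at a time, the adjusted p of the glycolysis list ranged from 0.0101 to 0.0886. Its call was lost with GC content and transcript length regressed out (camera adjusted p = 0.0795). Of 16 NRF2 antioxidant genes 8 were higher and 7 lower (list adjusted p = 0.863), with the heme oxygenase gene HMOX1 (1.68 ± 0.19) and TXN (0.59 ± 0.06) higher and SRXN1 (-2.97 ± 0.52), UGDH (-0.96 ± 0.08) and OSGIN1 (-0.67 ± 0.12) lower.

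All 23 genes of the fixed list of cytosolic ribosomal proteins rose, with a median of 0.89 (camera adjusted p = 5.92e-08; adjusted p = 0.641 with an estimated correlation). RPL18 rose from 499.6 ± 20.3 to 1123 ± 112 CPM (1.17 ± 0.08), RPLP1 by 2.18-fold and RPL19 by 2.14-fold; these genes have many processed pseudogenes that can share their reads. By symbol stem, a grouping chosen after the data were seen, 44 of 49 RPL genes were higher and 2 lower, and 32 of 42 RPS genes, which include ribosomal S6 kinase genes, were higher and 7 lower. All 13 mitochondrially encoded transcripts rose, with a median of 0.84 (camera adjusted p = 0.00118, and adjusted p = 0.641 with an estimated correlation). The estimated correlation between these genes was 0.90, so the 13 are not independent observations. MT-ND3 rose by 1.23 ± 0.16, MT-ND6 by 1.17 ± 0.10 and MT-ND1 by 1.01 ± 0.11. MT-ND6 lies opposite other mitochondrial transcripts, whose reads cannot be told apart from its own without strand. Nuclear oxidative phosphorylation genes were higher, with 14 of 20 higher and 3 lower, or 4 lower adjusted over the list alone (camera adjusted p = 0.0395; adjusted p = 0.682 with an estimated correlation). COX7C (1.01 ± 0.08), UQCRB (1.00 ± 0.09) and NDUFA1 (0.79 ± 0.10) rose, while the ATP synthase genes ATP5F1B (-0.47 ± 0.08) and ATP5F1A (-0.42 ± 0.08) and SDHA (-0.39 ± 0.07) fell. Leaving out 1 library at a time, the adjusted p of the oxidative phosphorylation list ranged from 0.0223 to 0.0551. Its call was lost with GC content and transcript length regressed out (camera adjusted p = 0.129).

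Of 16 fatty acid synthesis genes 10 were lower and 4 higher (list adjusted p = 0.0677 by camera and 0.000139 by fry). The elongase gene ELOVL7 fell from 96.1 ± 1.63 to 6.64 ± 0.476 CPM (-3.86 ± 0.08), and ELOVL5 (-1.13 ± 0.07) and the desaturase gene FADS2 (-0.95 ± 0.07) fell, while ELOVL6 rose from 11.7 ± 0.466 to 40.5 ± 4.23 CPM (1.79 ± 0.09) and ACSS2 by 1.33-fold. SREBF1 was higher by 0.17 ± 0.07 (adjusted p = 0.0355), with adjusted p of 0.00610 to 0.343 over the alternatives. Of 18 cholesterol genes 7 were lower and 3 higher (list adjusted p = 0.809). The squalene synthase gene FDFT1 (1.19 ± 0.09), INSIG1 (0.66 ± 0.09) and MSMO1 (0.36 ± 0.08) rose, and CYP51A1 (-1.85 ± 0.21) and SREBF2 (-0.46 ± 0.07) fell.

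Antigen presentation genes of MHC class I were higher, with 11 of 15 higher and 1 lower and a median of 0.59 (camera adjusted p = 0.0144; adjusted p = 0.641 with an estimated correlation). NLRC5, a transactivator of MHC class I genes, rose from 1.67 ± 0.0542 to 12.2 ± 0.880 CPM (2.86 ± 0.15), and HLA-F (1.55 ± 0.13) and HLA-B (1.26 ± 0.08) rose, although HLA genes are so alike and variable that their separate counts are uncertain. The peptidase gene ERAP1 fell (-1.15 ± 0.12). Type I interferon genes were 9 of 18 higher and 4 lower (list adjusted p = 0.161), with BST2 (2.11 ± 0.09), IFI6 (0.95 ± 0.13) and RIGI (0.91 ± 0.13) higher and MX1 (-1.94 ± 0.17) and OAS3 (-0.47 ± 0.11) lower. NF-kB inflammatory genes were 5 of 9 higher and 1 lower (list adjusted p = 0.102), with TNFAIP2 (1.30 ± 0.07), BIRC3 (0.86 ± 0.15) and RELB (0.81 ± 0.14) higher. The adhesion molecule gene ICAM1 was the 1 that was lower (-0.25 ± 0.09, adjusted p = 0.0271), with adjusted p of 0.00411 to 0.122 over the alternatives. Of 11 immediate early genes 9 were higher and 1 lower, with a median of 1.17 (camera adjusted p = 0.0193; adjusted p = 0.641 with an estimated correlation). EGR1 rose from 4.57 ± 1.73 to 16.9 ± 4.87 CPM (1.88 ± 0.23), FOSB by 3.08-fold and KLF6 by 2.53-fold, and NR4A1 fell (-0.27 ± 0.08).

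**Figure D2:**
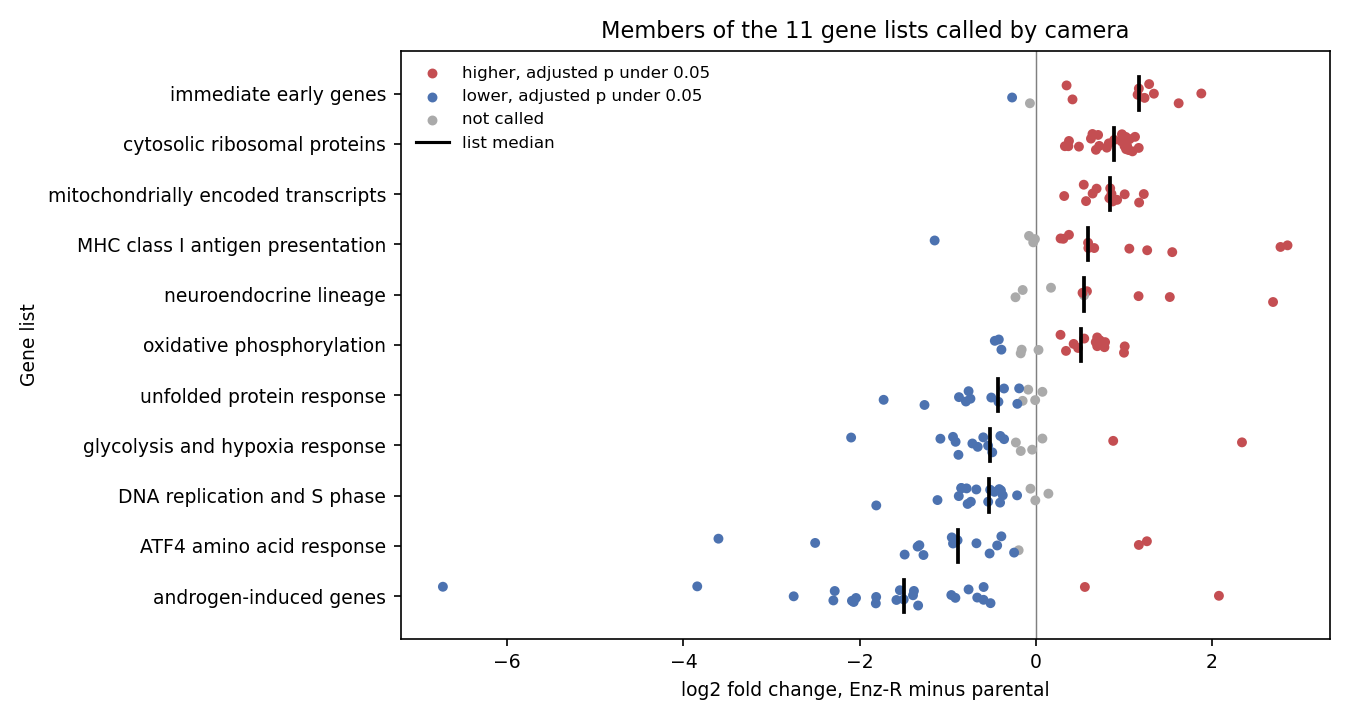
Log2 fold changes of Enz-R over parental for the tested members of the 11 gene lists called by camera, 1 line per list, with red and blue points for members called higher and lower, grey points for those not called and black bars for list medians. The medians run from -1.50 for the androgen-induced genes to 1.17 for the immediate early genes.

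Signalling genes moved both ways within each list. Of 17 Wnt genes 9 were higher and 6 lower (list adjusted p = 0.320). The non-canonical ligand gene WNT5A rose from 2.38 ± 0.0517 to 37.0 ± 4.16 CPM (3.96 ± 0.12), and RNF43 (1.38 ± 0.10) and LEF1 (0.93 ± 0.15) rose, while WNT3 (-1.72 ± 0.15), WNT7B (-0.68 ± 0.07) and AXIN2 (-0.59 ± 0.14) fell. MAPK and FGF output genes were 6 of 16 higher and 5 lower (list adjusted p = 0.992). The ERK phosphatase gene DUSP5 rose from 0.857 ± 0.338 to 13.9 ± 1.30 CPM (4.02 ± 0.20) and SPRY2 by 3.12-fold, while PHLDA1 (-3.32 ± 0.15), SPRY1 (-1.48 ± 0.18) and EPHA2 (-0.62 ± 0.09) fell. Notch genes were 3 of 13 higher and 7 lower (list adjusted p = 0.436). The ligand gene JAG1 fell from 89.7 ± 1.22 to 3.39 ± 0.427 CPM (-4.71 ± 0.09), and NRARP (-0.76 ± 0.12) and NOTCH3 (-0.53 ± 0.06) fell, whereas HES1 (1.18 ± 0.11), DLL1 (0.77 ± 0.10) and JAG2 (0.68 ± 0.06) rose. Drug efflux transporters were 2 of 8 higher and 2 lower (list adjusted p = 0.775). ABCC1 fell by 2.12-fold and ABCC5 was lower (-0.20 ± 0.06). The 2 higher members each rose at least 2-fold but did not reach the 5 CPM set for naming.

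Of the 34 lists tested, camera called 6 higher and 5 lower with its preset correlation and none with an estimated one. With the estimated correlation 1 list, that of the androgen-induced genes, had an unadjusted p under 0.05. Limma's fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 12 lists higher and 13 lower. Of the named genes tested, 165 of 178 kept their call and direction under every alternative in which they were tested. Some were not tested in all of them. With GC content and transcript length regressed out, the calls of RB1, HSD17B10, ITGA6, UBE2C, SREBF1, OAS3, ABCC5 and COL1A1 and of the glycolysis and oxidative phosphorylation lists were lost. Apart from the lists where another number is given, the counts of members adjusted over the list alone were the same as over all genes tested.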

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

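The counts of called genes kept within 1.5 times of their values under every alternative, at 5097 to 6475 higher and 5049 to 7094 lower, but with at least 50 counts required in 3 libraries the 2-fold changes fell to 1142 higher and 946 lower, as fewer genes were tested (14087), and 1 androgen-induced gene rose. Leaving out 1 library at a time gave 5629 to 6133 higher and 5813 to 6157 lower genes, 2133 to 2310 and 1700 to 1859 at 2-fold, and 4 to 6 lists higher and 4 to 5 lower. In these fits the adjusted p of the lists ranged from 0.0350 to 0.213 for the neuroendocrine lineage, 0.0101 to 0.0886 for glycolysis and 0.0223 to 0.0551 for oxidative phosphorylation. Values ranged from -0.22 to -0.10 for FOXA1, 0.17 to 0.34 for MYC, 0.13 to 0.22 for SREBF1, -0.31 to -0.17 for ICAM1 and -0.30 to -0.17 for COL1A1. With an estimated correlation camera called 0 lists higher and 0 lower, with adjusted p of 0.682 for glycolysis and oxidative phosphorylation and 0.641 for the other called lists, and fry called 12 and 13. With the replicate number as a block 6179 genes were higher and 6158 lower, the neuroendocrine list had adjusted p = 0.0564 and FOXA1 -0.15 (adjusted p = 0.0463), and no other call of a list or named gene changed. The deviations of same-numbered libraries correlated at 0.049, -0.0081 and 0.011, and 1 of 3 correlated best with its own number, so the numbers do not pair the samples. Total count scaling gave 42.3% of calls higher against 50.1%, and lost MYC (0.16) and SREBF1 (0.08), and called FOXA1 (-0.24). Limma-voom called FOXA1 (-0.15) and the no-filter fit lost SREBF1 (0.15). Correction for GC content and transcript length, chosen after the data were seen like thinning and leaving out mitochondrial genes, reversed HSD17B10 (-0.030) and ABCC5 (0.038), neither called. It lost RB1 (-0.06), ITGA6 (-0.05), UBE2C (0.14), SREBF1 (0.12), OAS3 (-0.24), COL1A1 (-0.16), glycolysis (adjusted p = 0.0795) and oxidative phosphorylation (adjusted p = 0.129), and of its calls 10337 were shared with the fit without it and 28 went the opposite way. Apart from the filter, the cause was not tested. Alternatives planned only for a table of normalised values (other pseudocounts, quantile or TMM-style rescaling of those values, limma without trend) were not run, since the table holds counts. At 15673404 to 28247038 counts per library, depth limits low genes such as NR3C1 and CHGA, and thinned counts gave 5892 higher and 5845 lower genes.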

Other observations

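Beyond the fixed lists, 175 gene families by symbol stem were tested with camera after the data were seen, and 11 passed at adjusted p under 0.05, 6 of them also with GC content and transcript length regressed out. None passed with an estimated correlation (adjusted p = 0.772 with an estimated correlation for each family named here). Of 10 HOXA genes, homeobox genes of 1 cluster on chromosome 7, 9 were lower in Enz-R, with a median log2 fold change of -1.60 (adjusted p = 0.0114; 0.0103 after the correction). HOXA10 was at -1.69 ± 0.14 and HOXA11 at -1.51 ± 0.13, while HOXA4 stood at 0.46 ± 0.26 and was not called. Of 11 genes of the carbonic anhydrase family, which includes members without enzyme activity such as CA8, 10 were higher, with a median of 1.07 (adjusted p = 0.0176; 0.0261 after the correction). CA1 rose from 0.722 ± 0.309 to 21.7 ± 15.5 CPM (4.85 ± 0.47) and CA8 from 1.88 ± 0.319 to 12.1 ± 1.54 CPM (2.67 ± 0.16), and CA1, CA2, CA3 and CA13 lie close together on chromosome 8. Of 26 small nucleolar RNA host genes 22 were higher and 2 lower, with a median of 0.56 (adjusted p = 0.00868; 0.0261 after the correction). Unannotated loci took 0.315% of counts in the parental and 0.391% in the Enz-R group, and of 696 tested 364 were higher and 96 lower.

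Windows of 25 neighbouring genes were also compared, a scan chosen after the data were seen, and 55 of 498 were shifted at adjusted p under 0.05, 32 higher and 23 lower in Enz-R. The most raised lay on chromosome X from 48.9 to 49.9 Mb (median 1.06, 24 of 25 genes above the median of all genes), including PQBP1 (1.42 ± 0.06) and PLP2 (1.21 ± 0.08). It also holds GAGE paralogs that share reads. The 2 neighbouring windows, from 30.7 to 46.9 and 46.9 to 48.9 Mb, had medians of 0.64 and 0.80. The most lowered lay on chromosome 1 from 19.9 to 23.4 Mb (median -0.81, 23 of 25 genes below), including ECE1 (-1.33 ± 0.08) and KDM1A (-0.85 ± 0.06), and on chromosome 20 from 2.66 to 4.19 Mb (median -0.77), including ATRN (-1.53 ± 0.07) and PTPRA (-1.36 ± 0.07). On chromosome 19, windows from 56.1 to 57.5 and 57.5 to 58.2 Mb, with 22 and 24 zinc finger genes, had medians of -0.76 and -0.74. The genes named in this paragraph were chosen after their values were seen.

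For the lower androgen-induced genes, the 1 test given here had its prediction written before its result was seen. With GC content and transcript length regressed out, the median of the list was -1.32, against -1.50 without, so the fall does not come from these trends alone. Protein levels and drug exposure were not analysed here.

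For the higher ribosomal protein genes, the test of scaling was chosen after the result was seen. The median of the list was 0.78 after correction for GC content and transcript length, which does not remove the rise. It was at lowest 0.79 over TMM, size factors and total count scaling. These scalings shift all genes nearly alike, with all-gene medians of 0.0077, 0.0074 and -0.084 in that order. The test of scaling therefore could not have removed the rise and decides nothing. The shortest eighth of transcripts had a median log2 fold change of 0.33 and the longest of -0.32, so short genes were higher in Enz-R in general. A difference in RNA quality or library preparation was not tested.

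For the runs of neighbouring genes, the test of gene dosage and the limits used for it were set after the result was seen, and its rule was changed once its correlations were known. The SD of window medians was 0.226 after correction for GC content and transcript length, above the highest of 1000 random gene orders (0.140), so these trends alone do not account for the runs. Adjacent windows correlated at 0.507 (highest in random orders 0.140), and medians of the weaker and the stronger expressed genes of a window at 0.539 (highest 0.179). This is in line with a hypothesis of gene dosage differences between the lines, but regional regulation predicts the same, and no DNA data were used.

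For the counts, the splits were planned before the data were seen. Of 10 ways to split the 6 libraries into 3 and 3, only the true one, 1 of 10, gave any called genes (6173 higher, 6150 lower, and 2095 and 1647 at 2-fold, against a highest of 0 elsewhere). Every other split puts libraries of both lines in each group. The difference between the lines then adds to the spread within groups and works against calls, so the 0 is no measure of chance. For lists, the other splits have no set direction, so the larger of the counts in the 2 directions was taken for each. Counting the true split, 2 of 10 reached its number called higher (6, highest other 7) and 3 of 10 its number called lower (5, highest other 7). The groups of every other split hold unequal numbers of libraries of each line, so part of the difference between the lines remains. Their list calls are therefore no measure of chance either. With 10 splits no share under 0.05 can be reached.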
